A study of Mus musculus with 2 samples.

How the data were processed

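Small RNA libraries of gastrocnemius tissue from adult male B6CASTF1/J mice of 18 to 20 months were measured by microRNA-seq, with inserts under 30 nt per the labels. B6CASTF1/J animals are the first-generation offspring of a cross between the C57BL/6J and CAST/EiJ strains. The deposited values are raw counts of reads per microRNA gene, 1 table per library, on the mm10 assembly with the GENCODE M21 annotation per the readmes beside the files. The aligner, the adapter trimming and the counting tool are not given in the sources used here. Each table of the authors holds 3 columns of counts, read from their values as counts without strand, on the gene's strand and on the opposite strand. The counts on the gene's strand were used. All 2202 gene identifiers matched the M21 annotation, from which symbols, coordinates and overlapping genes were taken. Where several genes overlap a microRNA gene on its strand, a protein-coding one is named first.

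The tables open with reads that belong to no gene, and these were kept out of library sizes and tests. Replicate 1 had 28387571 reads in its table, of which 15.7% were assigned to a microRNA gene, 73.8% were multimapping, 7.93% unmapped and 2.66% in no microRNA gene. Replicate 2 had 10872717 reads, of which 19.8% were assigned, 70.2% multimapping, 6.76% unmapped and 3.24% in no microRNA gene. No read was ambiguous between genes on the strand, and 4.55% and 5.30% were ambiguous without strand. Wilson 95% intervals of these shares were at most 0.0272 percentage points to either side, those of the shares of the most abundant genes at most 0.0637 points and those of the list shares at most 0.0524 points. Since multimapping reads are not part of the gene counts, microRNA genes with near-identical copies may be undercounted to an unknown degree. A precursor was taken to have a copy where it shares 20 bases with a microRNA gene at another locus, which 1087 of 2202 do. The length of 20 bases was kept as first chosen.

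CPM were computed over the counts assigned to microRNA genes and given as mean ± SD over the 2 libraries. Detection meant 2 CPM or more in both. Log2 ratios of replicate 2 over replicate 1 used CPM + 1 with edgeR's TMM scaling, which moved them by 0.0932 against plain totals. Genes with 10 or more counts summed over the libraries entered an exact two-sided binomial test of their counts given the scaled library sizes, with Benjamini-Hochberg adjustment and a threshold of 0.05. Intervals of single ratios are exact 95% Clopper-Pearson intervals of the counts. They leave out the 1 CPM added to the ratios, so at low counts they are not centred on the ratio given. The biological coefficient of variation was edgeR's common dispersion with an intercept only, with an interval from 50 bootstrap draws of genes. With 1 group there was no contrast between conditions, no pairing and no batch named in the labels.

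The 20 gene lists, the tests, the other settings to try and the rule for named genes were fixed before the data were examined. The rule named the 20 genes with the highest mean CPM, up to 4 members with the highest mean CPM of each list and every muscle-enriched member, the 5 genes furthest in each direction among those past the threshold with 100 or more counts, and the highest and lowest member of the microRNA families. The lists were muscle-enriched, myosin intronic, erythroid, endothelial, leukocyte, smooth muscle and mural, fibroblast and stroma, neural, epithelial, liver and endocrine, let-7, mir-30, mir-29, mir-181, mir-17 clusters, mir-23-27-24 clusters, Mir378 genes, stress and atrophy linked, Dlk1-Dio3 imprinted cluster and other imprinted. Each list's median log2 ratio was placed among 10000 random lists of the same size, as a description of these libraries with no p. Each random member was drawn from the 40 genes nearest in raw counts summed over the libraries, to which the deeper replicate 1 adds more.

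The other settings were the counts without strand, numbered copies left out, totals without the most abundant gene, other detection thresholds and count filters, pseudocounts of 0.1 and 5 CPM, DESeq2's median-of-ratios size factors or plain totals, and each library alone. Precursors sharing 20 bases left out, Mir22 left out and replicate 1 thinned to the depth of replicate 2 were added after seeing the data. In data simulated with counting error only, with 381 genes tested, the test of replicate 2 against replicate 1 called 70.7% of 58 genes changed 2-fold, 90.9% of 66 genes changed 4-fold and 1.56% of 257 unchanged genes. A simulated coefficient of variation of 0.5 was recovered as 0.480 over 386 genes. The tools were R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.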

Results

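MicroRNA-seq measured the small RNA of the gastrocnemius, the large calf muscle of the hindlimb, in adult male B6CASTF1/J mice of 18 to 20 months. The labels gave 1 group of 2 libraries, biological replicates 1 and 2, from separate biosamples and with inserts under 30 nt. Replicate 1 held 4442692 counts assigned to microRNA genes and replicate 2 held 2156222, a 2.06-fold difference in depth. A count of 0 allowed up to 0.675 CPM (counts scaled to a common library total) in replicate 1 and up to 1.39 CPM in replicate 2. The labels named no treatment, age series or second tissue, so the data describe the microRNA profile of this muscle and the differences between its 2 libraries. Nothing in the labels stated that the biosamples came from separate animals, so p-values measured only differences between these samples, which may be technical. Counts came from PCR-amplified reads, and the intervals and limits cover counting error only.

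Levels cover only the reads assigned to a microRNA gene, 15.7% of those of replicate 1 and 19.8% of those of replicate 2. Multimapping reads, 73.8% and 70.2%, were left out, so microRNA genes with copies may rank too low. Among assigned counts the profile was led by Mir378a, a microRNA gene in an intron of Ppargc1b, whose protein PGC-1beta regulates mitochondrial genes. Mir378a held 172860 ± 18207 CPM (SD, n = 2), or 17.3% ± 1.82 of assigned counts. Mir22 followed at 92026 ± 81527 CPM and Mir126a, the endothelial microRNA gene within Egfl7, at 79902 ± 34670 CPM. The let-7 genes Mirlet7g and Mirlet7i held 52535 ± 12077 and 49290 ± 13514 CPM, and Mir143, known from smooth muscle, held 48790 ± 3910 CPM. Mir23a, Mir23b, the skeletal muscle microRNA gene Mir206 and Mir26b completed the 10 most abundant genes, at 41199 ± 17488, 37373 ± 10560, 36675 ± 35165 and 35380 ± 10006 CPM. The next were Mir99a at 33058 ± 1300 CPM, Mir30a at 27082 ± 7471, Mirlet7b at 24525 ± 8981, Mirlet7d at 20728 ± 6929 and Mir10b at 19938 ± 772 CPM. Mir100 at 16909 ± 207 CPM, Mir139, Mir29a, Mir149 and Mir21a made up the rest of the 20 most abundant genes.

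The 10 most abundant genes took 64.6% ± 0.473 of assigned counts (SD, n = 2) and the 20 most abundant took 84.3% ± 0.944. Of the 20, 9 lay in introns of other genes, 7 overlapped exons and 4 were intergenic in the GENCODE M21 annotation. At 2 CPM or more in both libraries, 324 of 2202 microRNA genes were detected, 357 in replicate 1 and 348 in replicate 2. Of the 324, 143 were intronic, 80 exonic and 101 intergenic, and 1559 of the 2202 genes had no count in either library. Mir378a and Mir126a each overlap a microRNA gene on the other strand, so their levels rest on the strand-specific counts. Without strand, Mir378a had 0 counts and Mir126a had 11 and 1.

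**Figure D1:**
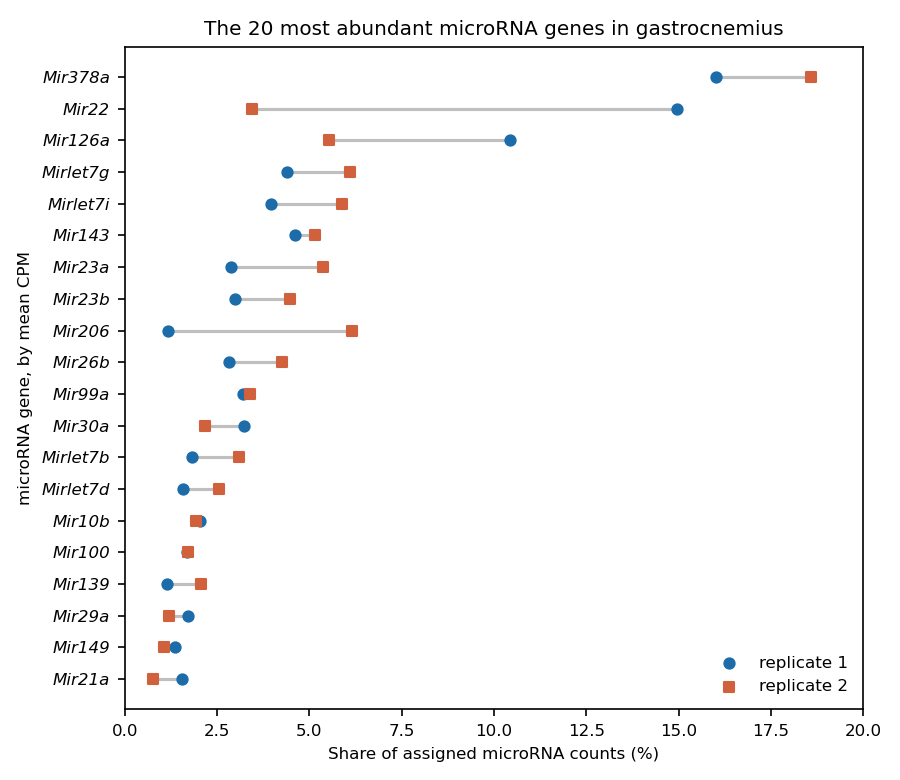
Share of assigned microRNA counts (percent, horizontal axis) of the 20 most abundant microRNA genes, ordered by mean CPM, in replicate 1 (circles) and replicate 2 (squares), with a line joining the 2 libraries. Mir22 stood at 15.0% in replicate 1 and 3.44% in replicate 2 and Mir206 at 1.18% and 6.15%, while Mir378a led both libraries.

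The main genes lay at the following places of the mm10 assembly, 1-based. Mir378a (ENSMUSG00000105200.1) lies on chromosome 18 from 61397835 to 61397900, minus strand, in an intron of Ppargc1b. Mir22 (ENSMUSG00000065529.1) lies on chromosome 11 from 75463716 to 75463810, plus strand, and overlaps an exon of a Tlcd2 transcript. Its precursor sequence is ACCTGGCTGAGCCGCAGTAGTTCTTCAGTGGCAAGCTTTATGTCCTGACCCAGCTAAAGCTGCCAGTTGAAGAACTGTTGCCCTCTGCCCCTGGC. Mir126a lies on chromosome 2 from 26591357 to 26591429, plus strand, and overlaps an exon of Egfl7. Mir206 lies on chromosome 1 from 20679010 to 20679082, plus strand, and overlaps an exon of the gene model Gm28653. Its precursor sequence is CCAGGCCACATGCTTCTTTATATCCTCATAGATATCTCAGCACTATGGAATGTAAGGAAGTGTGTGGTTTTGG.

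The muscle-enriched list, the group of microRNA genes known for their expression in striated muscle, took 4.11% ± 3.49 of assigned counts (SD, n = 2). Its share was 1.64% in replicate 1 and 6.57% in replicate 2, and Mir206 made up most of it in both. Mir206 held 11810 CPM in replicate 1 and 61540 CPM in replicate 2, Mir486, in an intron of Ank1, 3829 ± 583 CPM, and Mir499, in Myh7b, 295 ± 316 CPM. Mir1a-2, one of a pair of loci of the best known muscle microRNA, held 132 ± 72.3 CPM, and Mir1a-1 held 13.0 ± 8.61 CPM. Mir133a-1 and Mir133a-2 held 13.0 ± 2.63 and 3.07 ± 1.07 CPM, Mir133b 25.8 ± 14.2 CPM, and Mir133c had no count. The Mir1a and Mir133a loci share stretches of 20 bases with other loci and 73.8% and 70.2% of reads in the 2 libraries were multimapping and left unassigned, so their levels are uncertain.

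Lists of other cell types took shares of very different size. The endothelial list, in effect Mir126a, took 7.99% ± 3.47 of counts, and the smooth muscle and mural list, with Mir143 and Mir145a, 5.28% ± 0.565. The leukocyte list took 0.296% ± 0.0952, led by Mir150 at 1425 ± 485 CPM and Mir155 at 1239 ± 546 CPM. The fibroblast and stroma list took 0.103% ± 0.0875, nearly all of it Mir214 at 1009 ± 864 CPM. The erythroid list took 0.0443% ± 0.0473, the neural list 0.0358% ± 0.00395, the liver and endocrine list 0.0275% ± 0.0259 and the epithelial list 0.0215% ± 0.00139. Replicates 1 and 2 gave 0.165% and 0.0416% for the fibroblast and stroma list, 0.0777% and 0.0109% for the erythroid list and 0.00914% and 0.0458% for the liver and endocrine list. The erythroid share was thus the highest of the last 4 in replicate 1 and the lowest in replicate 2. Against the muscle-enriched list, the endothelial list was higher by 2.67 on the log2 scale in replicate 1 and lower by 0.25 in replicate 2, so their order differed between the libraries. Of the 12 muscle-enriched genes 6 share 20 bases with another locus, while no endothelial gene does. Multimapping reads left out could thus lower the muscle-enriched share more than the endothelial one, so the order of these lists is uncertain. Copies were sought only as exact stretches shared with microRNA genes at other loci, so reads of Mir126a could have been left out too. With 2 libraries no exact two-sided sign-flip test between lists can give a p under 0.5.

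Among the microRNA families, let-7 took 16.0% ± 4.25 of counts (SD, n = 2), with all 12 members at 2 CPM or more in both libraries. The mir-23-27-24 clusters took 8.45% ± 2.70, the mir-30 family 4.38% ± 1.14, the mir-29 family 1.71% ± 0.528, the mir-17 clusters 0.465% ± 0.0990 and the mir-181 family 0.120% ± 0.0182. Within let-7, Mirlet7g was the highest member and Mirlet7a-2 the lowest, at 117 ± 2.47 CPM, and Mirlet7a-2 shares 20 bases with other let-7 loci. Within the mir-30 family Mir30a stood against Mir30c-1 at 66.9 ± 31.3 CPM, and within the mir-29 family Mir29a at 14538 ± 3485 CPM stood against Mir29b-2 at 24.2 ± 10.6 CPM. Mir30c-1 and Mir29b-2 share 20 bases with Mir30c-2 and Mir29b-1, so their low levels are uncertain. Mir92-1 led the mir-17 clusters at 1562 ± 583 CPM, and Mir19a and both Mir19b loci had no count in either library. The Mir19b loci share 20 bases with each other, so their reads could have been left unassigned as multimapping. The list of Mir378 genes took 17.3% ± 1.82, nearly all of it Mir378a. The stress and atrophy linked list took 10.4% ± 8.69 (16.6% in replicate 1 and 4.27% in replicate 2), of which Mir22 and Mir21a (11569 ± 5496 CPM) made up nearly all. The Dlk1-Dio3 imprinted cluster took 0.290% ± 0.0444, led by Mir127 at 958 ± 15.1 CPM, and the other imprinted genes, led by Mir335 at 430 ± 37.3 CPM, took 0.0530% ± 0.000308.

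Replicate 2 against replicate 1 asks how far microRNA levels differed between samples that carry the same labels. Levels were correlated between the libraries, with Spearman's rho 0.926 and Pearson's r 0.955 across 380 genes with 10 or more counts, which are not independent replicates. Levels nevertheless differed for many genes. The SD of the log2 ratios was 1.13, a factor of 2.20, over the 228 genes with 100 or more counts. Among genes with 100 or more counts, Mir122, the liver microRNA gene, Mir26a-1, Mir770, Mir499 and Mir206 were the furthest above in replicate 2, and Mir301, the erythroid gene Mir144, Mir195a, the epithelial gene Mir205 and Mir152 the furthest above in replicate 1.

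Of the 380 genes tested, 235 differed past an adjusted p of 0.05 in the exact two-sided binomial test with Benjamini-Hochberg adjustment, 115 higher in replicate 2 and 120 higher in replicate 1. A difference of 2-fold or more was found for 109 of them, 46 higher in replicate 2 and 63 higher in replicate 1. The test compares these libraries, not conditions, and takes only counting error into account. The biological coefficient of variation from edgeR was 0.529 (0.451 to 0.583, 95% bootstrap interval over genes). Chi-square per degree of freedom was 1359, so the files did not hold a single library deposited more than once.

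**Figure D2:**
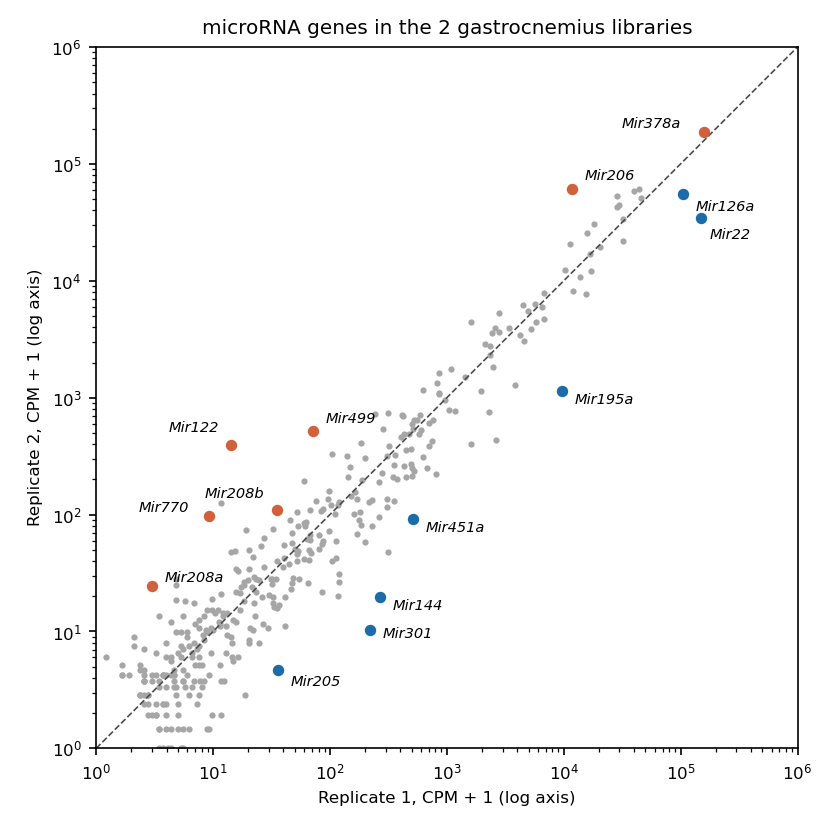
CPM + 1 of each microRNA gene with 10 or more counts in replicate 1 (horizontal log axis) and replicate 2 (vertical log axis), with equality as a dashed line and selected named genes in colour. Orange points, among them Mir206, Mir499 and Mir122, had a log2 ratio above 0 and blue points, among them Mir22, Mir195a and Mir144, had one below 0.

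Mir122 held 13.3 CPM in replicate 1 and 396 CPM in replicate 2, a log2 ratio of 4.89 (95% counting interval 4.61 to 5.40). The log2 ratio was 3.50 (3.17 to 4.09) for Mir26a-1, which shares 20 bases with Mir26a-2, and 3.47 (3.12 to 4.17) for Mir770, in an exon of Meg3. Mir206 was 5.56-fold higher in replicate 2, at a log2 ratio of 2.47 (2.46 to 2.49). On the other side, Mir301, in an intron of Ska2, held 218 CPM in replicate 1 and 9.28 CPM in replicate 2, a log2 ratio of −4.33 (−5.18 to −3.83). Mir195a held 9660 and 1130 CPM (log2 ratio −3.002), Mir205 34.9 and 3.71 CPM (−2.85) and Mir152, in an intron of Copz2, 314 and 47.3 CPM (−2.61). Mir22 was 4.08-fold higher in replicate 1, at 149674 CPM against 34378 CPM. Mir378a, Mir143, Mir99a, Mir10b and Mir100, also among the 20 most abundant genes, had log2 ratios of 0.31, 0.26, 0.17, 0.01 and 0.12, the last −0.028 with no count filter. For Mir10b the difference was not past the threshold (adjusted p = 0.140, exact binomial test).

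All 3 members of the myosin intronic list were higher in replicate 2, and the muscle-enriched list that contains them was divided. Mir499, in Myh7b, held 70.9 CPM in replicate 1 and 518 CPM in replicate 2, a log2 ratio of 2.95 (2.78 to 3.15). Mir208b, in Myh7, the slow myosin heavy chain gene, held 34.0 and 108 CPM (1.73), and Mir208a, in Myh6, held 2.03 and 23.7 CPM (3.10). The list's share of counts was 0.0107% (Wilson 95% interval 0.00977 to 0.0117) in replicate 1 and 0.0650% (0.0617 to 0.0685) in replicate 2. Its median log2 ratio of 2.95 lay at the 99.9th percentile of 10000 random lists matched on summed counts. Mir499 lies on chromosome 2 from 155622880 to 155622958, plus strand, with the precursor sequence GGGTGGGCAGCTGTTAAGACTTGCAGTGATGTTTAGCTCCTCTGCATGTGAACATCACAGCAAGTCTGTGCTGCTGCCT. Mir208b and Mir208a lie on chromosome 14, minus strand, from 54975700 to 54975776 and from 54949060 to 54949142.

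In the whole muscle-enriched list, 4 of 10 tested members were higher in replicate 2, 4 in replicate 1 and 2 did not pass. Its median log2 ratio was −0.26 (24.7th percentile) while the mean was 0.59, so the median and mean differed in sign. The median also changed sign with the genes counted. It was 0.69 (98.2nd percentile) with the counts without strand, 2.16 (100th) with numbered copies left out and 2.56 (99.99th) with precursors sharing 20 bases left out, the last chosen after seeing the data. Mir206 and the myosin intronic genes were those higher in replicate 2. Mir1a-2 (log2 ratio −1.07), Mir1a-1 (−1.25), Mir133b (−1.04) and Mir486 (−0.22) were higher in replicate 1. Of the members higher in replicate 1, all except Mir486 share 20 bases with another locus. Mir486 overlaps the microRNA gene Mir3107 on the other strand, and overlapping genes were not part of the search for copies.

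The erythroid genes Mir451a and Mir144, neighbours on chromosome 11, were both higher in replicate 1. Mir451a held 509 CPM against 90.0 CPM (log2 ratio −2.39, −2.63 to −2.19) and Mir144 held 268 CPM against 18.6 CPM (−3.69, −4.25 to −3.30). Their median log2 ratio of −3.04 lay at the 0.15th percentile of random lists. Of the epithelial list, 3 of 5 tested members were higher in replicate 1 and 1, Mir203, was higher in replicate 2, with a median of −1.86 (0.08th percentile). The list's share of counts, most of it Mir203, went the other way, at 0.0205% in replicate 1 and 0.0225% in replicate 2. Its median rests on low counts, since in replicate 2 Mir200b had 2 counts and Mir429 had 1 count. Their log2 ratios were −2.55 (−6.54 to −1.52) and −1.86 (−8.56 to −0.54). The intervals leave out the added 1 CPM, which shrinks the ratios of such low counts. With a pseudocount of 5 CPM in place of 1 CPM the epithelial median was −0.77.

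The let-7 family was higher in replicate 2 for 9 of 12 members, lower for 1, Mirlet7f-2 (log2 ratio −0.05, and 0.0098 with replicate 1 thinned), and not past the threshold for 2, Mirlet7c-1 (0.00) and Mirlet7a-2 (0.13). The median was 0.61 (98.6th percentile), with Mirlet7b at 0.86, Mirlet7i at 0.66 and Mirlet7g at 0.57. In the Dlk1-Dio3 imprinted cluster, 15 of 45 tested genes were higher in replicate 1, 6 were higher in replicate 2 and 24 did not pass, with a median of −0.46 (1.62nd percentile). Mir411 (−0.78) and Mir379 (−0.62) were lower in replicate 2, Mir127 was at 0.06 without passing, and Mir770 went the other way. With replicate 1 thinned to the depth of replicate 2, an alternative chosen after seeing the data, the median of this cluster was −0.24. The neural list had 2 of 4 tested members higher in replicate 2, Mir137 (1.85) and Mir219a-2 (2.03), 1 higher in replicate 1, Mir219a-1 with 1 count in replicate 2, and Mir338 at 0.13 without passing. Its median was 0.99 (97.6th percentile). With the counts without strand Mir137 alone stayed in the list, at 1.85.

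These 6 of the 20 lists lay outside the central 95% of random lists, where chance alone would put 1 of 20 lists of unrelated genes. Many lists hold locus or family mates, whose ratios were closer to each other than those of random pairs, so more than 1 of these lists is expected there by chance. Only the myosin intronic and erythroid lists lay outside it under every alternative run. With the counts without strand Mir451a had no count, and the erythroid list, Mir144 alone, lay at the 2.38th percentile. The let-7 family fell inside with the counts without strand (92.8th percentile), numbered copies left out (96.7th) or precursors sharing 20 bases left out (97.3rd). The neural list fell inside with either kind of copies left out (92.2nd and 93.2nd) or a pseudocount of 0.1 CPM (97.0th). The Dlk1-Dio3 cluster fell inside with precursors sharing 20 bases left out (2.74th), replicate 1 thinned (4.25th) or a pseudocount of 5 CPM (2.52nd), as did the epithelial list with 5 CPM (4.09th). The endothelial list (Mir126a, log2 ratio −0.82, 10.03rd percentile), the fibroblast and stroma list (median −0.90, 10.35th) and the mir-29 family (−0.60, 4.97th) were lower in replicate 2 within that range. Mir214 had the lowest ratio in the fibroblast and stroma list (−1.93), whose 3 tested members were 2 higher in replicate 1 and 1 not passing, or 3 higher in replicate 1 when adjusted over the list alone. The liver and endocrine list (0.84, 94.97th) moved outside the central range with numbered copies left out (1.60, 98.9th) or precursors sharing 20 bases left out (1.69, 99.1st). It and the smooth muscle and mural list (0.63, 87.2nd), the stress and atrophy linked list (0.34, 78.9th; mean −0.11, of the other sign) and the leukocyte list (0.28, 72.4th) lay above 0. Of the leukocyte genes Mir155 (1.02) and Mir150 (0.80) were higher in replicate 2, and Mir142 (−0.69) and Mir223 (−0.23) in replicate 1. The mir-23-27-24 clusters (0.27, 70.7th), other imprinted genes (0.27, 75.4th), the mir-181 family (0.12, 68.2nd), the Mir378 genes (−0.08, 38.2nd), the mir-30 family (−0.44, 11.01th) and the mir-17 clusters (−0.52, 12.9th) completed the lists. Adjusted over the list alone, the counts higher and lower were as over all genes in each list except the fibroblast and stroma list and the neural list, where 3 members in place of 2 were higher in replicate 2.

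**Figure D3:**
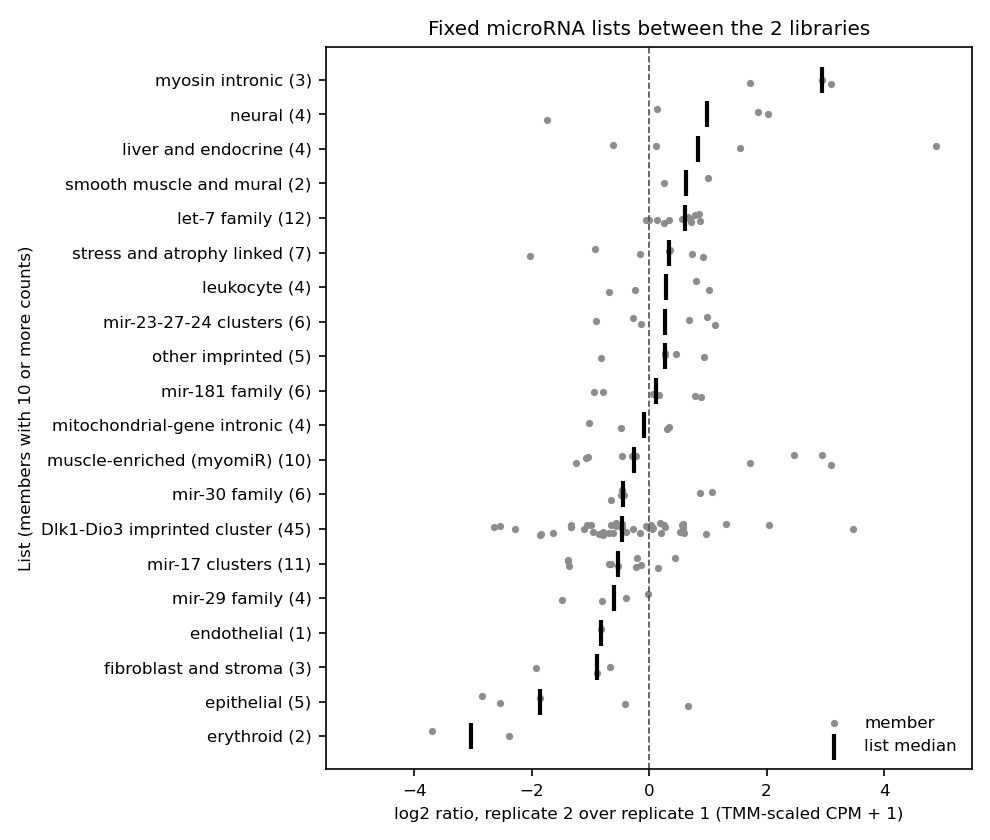
Log2 ratio of replicate 2 over replicate 1 (TMM-scaled CPM + 1, horizontal axis) of each list member with 10 or more counts (grey points) and the list median (black bars), with the number of members beside each list name. The myosin intronic median lies at 2.95 and the erythroid median at −3.04, at the top and bottom of the 20 lists.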

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

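Reads outside the gene counts stood above the limit that a count of 0 allows in both libraries. Multimapping reads were 73.8% of the reads of replicate 1 and 70.2% of those of replicate 2, and reads in no microRNA gene were 2.66% and 3.24%.

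Counts on the opposite strand were few, and 3 genes without a microRNA gene on that strand had more than 3 of them in both libraries. Mir675, in an exon of the imprinted gene H19, had 26 and 7 such counts in replicates 1 and 2, against 7 and 8 on its own strand. Mir122 had 35 and 10, against 59 and 854 on its own strand. Mirlet7b had 4 and 6, against 80743 and 66573. No explanation of these counts was tested.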

How the results depend on the processing

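The 324 detected genes, the muscle-enriched share, the coefficient of variation, the 235 genes past the threshold and the list medians moved by less than their spread (1 SD between the libraries, the bootstrap interval for the coefficient, or 1 SD of random lists for list medians) or, for counts, by less than 1.5 times under every alternative, except the list medians below. The share of counts in the 10 most abundant genes, 64.6% with an SD of 0.473, was 62.9% with the counts without strand, 65.7% with numbered copies left out, 61.2% without the most abundant gene in the total and 66.7% without precursors sharing 20 bases (like thinning and leaving out Mir22, added after seeing the data). These shifts follow from the genes or totals that each choice removes. The correlation between the libraries, a Spearman's rho of 0.926, was 0.885 with no count filter, which adds genes of few counts.

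The myosin intronic median, 2.95, was 2.08 with a pseudocount of 5 CPM, which shrinks the ratio of low genes. The epithelial median, −1.86, was −2.94 with 0.1 CPM and −0.77 with 5 CPM likewise. The neural median, 0.99, was 1.85 with the counts without strand, where Mir137 alone is left, and 1.63 with replicate 1 thinned. The Dlk1-Dio3 median, −0.46, was −0.24 with replicate 1 thinned and −0.25 with a pseudocount of 5 CPM, and for thinning the cause was not tested. The muscle-enriched median, −0.26, was 0.69 with the counts without strand, where Mir486 and Mir1a-2 have no count, 2.16 with numbered copies left out and 2.56 without precursors sharing 20 bases. The liver and endocrine median, 0.84, was 1.60 and 1.69 under these last 2 choices. Without precursors sharing 20 bases, the fibroblast and stroma median, −0.90, was −1.85, that of the mir-181 family, 0.12, was 0.56 and that of the mir-17 clusters, −0.52, was −0.16. These shifts follow from the members left out. The Mir378 median changed sign, from −0.08 to 0.06, with replicate 1 thinned. Of 20 lists, 6 lay outside the central 95% of random lists as reported, 4 with a pseudocount of 5 CPM and 5 of 19 without precursors sharing 20 bases, where no mir-23-27-24 gene is left.

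Over 901 alternatives of the log2 ratios of 109 named genes, 836 kept the direction and the side of the threshold, 22 lost the threshold, 20 gained it and 23 changed sign. Of the last, only Mir100 (0.12) and Mirlet7f-2 (−0.05) were past the threshold as reported. With no count filter, which moves all ratios by −0.146 through TMM scaling, log2 ratios were −0.028 for Mir100, −0.132 for Mir10b, −0.085 for Mir127, −0.012 for Mir338, −0.010 for Mirlet7a-2, −0.084 for Mir181c, −0.0091 for Mir375 and −0.144 for Mirlet7c-1. With plain totals they were −0.079 for Mir10b, −0.032 for Mir127, −0.031 for Mir181c and −0.091 for Mirlet7c-1. Those of Mir10b and Mirlet7c-1 were −0.025 and −0.037 with median-of-ratios size factors, −0.015 and −0.028 without Mir22 and −0.0085 and −0.021 with the counts without strand, where that of Mir675 was −0.022. That of Mir29b-1 was 0.015 at 2 CPM in both libraries and 0.030 with replicate 1 thinned, which put Mir375 at −0.103 and Mirlet7f-2 at 0.0098. For the counts without strand and thinning the cause was not tested. Of the genes past the threshold, 48.9% were higher in replicate 2, between 42.2% with no filter and 54.5% with replicate 1 thinned. Each library alone gives shares within 1 SD of the mean of 2 by construction, which says nothing of stability. Depth limits genes near the floors of 0.675 and 1.39 CPM, where single counts move a ratio.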

Other observations

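Mir10b, Mir152, Mir195a and Mir301 were named by the fixed rule. The other genes of the first 2 paragraphs, the test of the low Mir1a and Mir133a counts, the tests of depth and of the share of Mir22 for the myosin genes, and the tests of locus mates and family mates for the spread between the libraries were chosen only after related values had been seen. Several microRNA genes lie within the Hox clusters, whose genes set position along the body and limb axes. Mir10b, in an intron of Hoxd3, held 19938 ± 772 CPM (SD, n = 2), Mir196b, in an exon of Hoxa9, 5230 ± 359 CPM, and Mir196a-2, in an intron of Hoxc5, 3676 ± 418 CPM. Mir10a held 3203 ± 603 CPM and Mir615, in an intron of Hoxc5, 909 ± 182 CPM. Their log2 ratios of replicate 2 over replicate 1 were 0.01, 0.23, 0.33, 0.48 and −0.32. Mir196a-1, which shares 20 bases with Mir196a-2, held 13.4 ± 6.58 CPM, with a log2 ratio of 1.05 (95% counting interval 0.46 to 1.81).

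Some families and neighbours moved together and others moved apart. Mir148a, Mir148b and Mir152, of 1 family at separate loci, were all higher in replicate 1, with log2 ratios of −2.45 (95% counting interval −3.002 to −2.05), −1.30 (−1.67 to −0.98) and −2.61 (−2.94 to −2.35). Mir221 and Mir222, neighbours on chromosome X, were higher in replicate 2 at 1.67 and 1.32. Mir15a and Mir16-1, in Dleu2, were higher in replicate 1 at −2.50 and −1.33. Mir15b and Mir16-2, in Smc4, went apart at −0.81 and 1.24, and both Mir16 loci share 20 bases with another locus. Mir195a and its neighbour Mir497 stood at −3.002 and −0.73, and Mir301 stood at −4.33 while Mir130a, of the same seed family, stood at 0.42.

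The 4 loci Mir1a-1, Mir1a-2, Mir133a-1 and Mir133a-2 together held only 983 and 219 counts. Reads shared between copies stay open as a candidate explanation, since across 5 families other than the muscle-enriched list precursors sharing 20 bases with another locus differed from their relatives by a mean of −3.48 on the log2 scale (one-sided stratified permutation p = 0.0031). The mean log2 level was 8.53 against 13.9 in the let-7, 7.61 against 12.2 in the mir-30 and 7.21 against 13.8 (1 relative) in the mir-29 family, but 6.22 against 6.38 in the mir-181 family and 4.19 against 4.96 in the mir-17 clusters. Mir378a, Mir23a and Mir23b have such a stretch too and were among the 10 most abundant genes, and how many of their reads were left unassigned was not tested. No biological explanation was tested, because the design holds 1 group.

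The myosin intronic genes Mir499, Mir208b and Mir208a were higher in replicate 2, with a median log2 ratio of 2.95. A trend with precursor GC content and the share of Mir22 are argued against as the whole cause. The median was 3.02 after removing a trend with precursor GC content (99.9th percentile of random lists), and GC content of the reads was not tested. With replicate 1 thinned to the depth of replicate 2 the median was 2.83 (99.8th percentile). Thinning keeps the proportions of replicate 1, so it could hardly have moved the ratios and does not decide on depth. The lowest lower 95% counting bound of the members' log2 ratios was 1.45, which rests on the same counts as the difference itself. The shares of Mir22 could shift all other genes by only 0.183, and other single genes were not tested. What caused the difference stays open, and no biological explanation was tested because the design holds 1 group. In the same comparison Mir122 and Mir206 were 29.6-fold and 5.56-fold higher in replicate 2 and the erythroid median was −3.04. Mir208a rests on 9 and 51 counts.

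The log2 ratios between the libraries spread well beyond counting error. A steady trend with precursor GC content is argued against as the whole cause, since the log2 ratio followed it with a Spearman's rho of 0.0523 across 228 genes (permutation p = 0.431). GC content of the reads themselves was not tested. Different amounts of primary transcript stay open, since locus mates differed by a median of 0.620 against 0.953 for shuffled ratios (99 pairs, one-sided permutation p = 0.00596), and by 0.681 against 0.996 over 68 pairs without precursors sharing 20 bases (permutation p = 0.0356). Many of these locus pairs lie in the Dlk1-Dio3 cluster, and the test was not run without it. Families were told apart by gene number, so locus mates with different numbers could still be related in sequence. A difference that follows the microRNA sequence, in the tissue or in library making, may add to any difference in primary transcript. Family mates at other loci differed by 0.495 against 0.955 for shuffled ratios (118 pairs, one-sided permutation p = 0.00056). Without precursors sharing 20 bases they differed by 0.228 against 1.01 over 26 pairs (permutation p = 0.00022). Many of these family pairs are let-7 genes, whose median log2 ratio was 0.61, and the test was not run without them. Pairs share genes, reads of relatives that differ at few bases could be assigned to each other, and variation between animals was not tested.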
